A study of Drosophila melanogaster with 10 samples.

How the data were processed

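DNA from embryos of 9 deletion genotypes and of wild type Oregon R was compared on 10 2-colour oligonucleotide arrays with DNA of mixed-stage Oregon R embryos. The Cy5 channel held the deletion or wild type DNA and the Cy3 channel the reference on every array, per the labels, with no dye swap. Deletion embryos were 3.5 to 8 h old, 4- embryos 23 to 24 h and wild type embryos 2.5 to 3.5 h, per the stage labels; another note in the labels gives a wider late range for 4-. Each genotype had 1 array. Groups were taken from the labels, and each arm was called absent where the label names its loss.

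The scanner files hold linear intensity values per spot, per the file headers, written by Agilent Feature Extraction 9.5.3.1. Its processed signals are background-subtracted, detrended in space and by a multiplicative fit, and dye-normalized by the method that the header codes as 6. The same files hold a log10 ratio of Cy5 over Cy3, per the file headers. The deposited value table holds 1 column of log2 ratios per array; its direction was checked against the scanner ratios, but its exact scale and centring are not stated. Against the scanner log2 ratios its columns had r between 0.885 and 0.964 and slopes between 0.455 and 0.774. The column medians were 0.23 for 2L-, 0.14 for 2R-, -0.20 for 2En-, 0.05 for 3L-, 0.01 for 3R-, -0.35 for 3En-, 0.08 for 4-, -0.04 for X-, -0.10 for XY- and 0.09 for WT. The submitters' processing notes name limma without a version. Probe positions are those of the array files on dm3.

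Each array held 105072 spots, 103747 of them not controls, for 83472 distinct probes. Control spots were left out, as were spots marked as outliers, which were 0.939% to 3.58% of spots per array. The main value was log2 of processed Cy5 over processed Cy3, averaged over the spots of a probe and centred on the median of each array, with no loess or quantile step because whole arms shift one way. Probes were kept where the Cy3 signal was well above background in a share of 0.5 or more of its spots on all 10 arrays, which left 80060. Cy3 was well above background at 97.9% to 99.0% of spots per array and Cy5 at 93.0% to 99.5%. Median signals per array were 182 to 950 in Cy3 and 143 to 1046 in Cy5. Array values carry no counts, so precision is limited by the number of arrays.

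Gene names come from the array files. Where a probe's accession was in the RefSeq gene table of Release 6 (used for names only), its symbol was updated: 17394 of 23447 catalog probes matched, and 5103 of these took a different name. Gene values are medians over a gene's probes, and positions are the span of those probes. Before the data were examined, the following were fixed: the comparisons, the tests, the gene lists per chromosome and the rule for named genes. That rule takes the genes of the lists with 3 or more probes and, per arm, the 10 genes in placed heterochromatin with the most probes. Examples were chosen among these after their values were seen, and ci, ORY, Ppr-Y and other listed genes with 1 or 2 probes were named after it too.

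Arm and scaffold medians were compared by a two-sided exact permutation test of 2 against 8 arrays, with Benjamini-Hochberg adjustment; 45 choices of 2 arrays make 0.0444 the smallest p. Single probes were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 1 fit of all arrays per absent arm, with X-, XY- and the other arrays as classes of their own for the Y. For chromosome 4, for the Y and for X- the class of interest is 1 array, assumed to vary like the others. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of 1 or more. A gene was counted as fallen when its median difference was -1 or lower and most of its probes were called. Tested on simulated data with 200 changed probes among 80060, a comparison of 2 against 8 arrays recovered 56%, 82%, 98% and 94% of probes changed by -1.5, -2, -3 and -4, with 1 false call. A comparison of 1 against 9 recovered 30%, 72%, 82% and 98%, with 7 false calls. The simulated noise was independent and normal, with SDs from 3R probes on arrays that carry 3R. It held no other absent arms and no slide effects, which eases recovery. It also held fewer changed probes than were called without X, 2L, 2R, 3L or 3R, which makes an adjusted p harder to pass. These shares are therefore rough guides and not bounds. In the real data 63.6% of tested chromosome 4 probes were called at a median difference of -4.475, and 83.4% of X probes at -2.95.

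Windows of 10 kb with 5 or more probes in U and Uextra, and single probes without a position, were assigned by the set of arrays at 1 or more (log2) below the median of the 10. Proximal profiles used windows of 250 kb with 3 or more probes over 3 Mb of euchromatin and the placed scaffold. Slide and scan session were taken from the files and treated as batches. Repeat probes were found by matching units of known satellites over at least 30 of the 60 bases of a probe, or 5 shared words of 12 bases for the complex satellite of the X.

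Alternatives were normexp with an offset of 50 on mean and background signals, centring on the euchromatic arms that a genotype keeps, loess within arrays, the deposited table, no filter on dim probes, and no saturated probes. For the probe fits they were also thresholds of 0.5 and 1.5, adjusted p under 0.01, array weights, an additive fit of all arms, slide as a random block, and each array left out. Windows, medians and retained dose had alternatives of their own. Chosen after the data were seen were the removal of a GC trend, scan and slide as fixed blocks, the 6 arrays of scan 2 alone, assignment of single probes, and gene lists with 1 or more probes. The proximal window size was chosen then as well. Further tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.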

Results

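Array comparative genomic hybridisation was run on DNA from Drosophila melanogaster embryos that lacked a whole chromosome or a chromosome arm. Such embryos come from crosses between stocks with compound chromosomes, in which homologous arms are joined to one centromere, so that some eggs and sperm carry none of that arm. The 10 arrays held 1 genotype each: embryos without the left or the right arm of chromosome 2 (2L-, 2R-) or all of it (2En-), the same for chromosome 3 (3L-, 3R-, 3En-), without chromosome 4 (4-), without the X (X-), without X and Y (XY-), and wild type Oregon R blastoderm embryos (WT). No genotype had a second array. The replicates of an absent arm were therefore the 2 genotypes that both lacked it, against the 8 that carried it. Each array compared 100 to 150 such embryos, labelled with Cy5, with a reference of Oregon R embryos of 0 to 8 h, labelled with Cy3. The 80060 probes that were kept comprised 3729 on the X, 4048 on 2L, 4604 on 2R, 4392 on 3L, 5604 on 3R and 234 on chromosome 4, and 56671 without a position in the files. The others lay on heterochromatic scaffolds, on collections of unlocalised sequence (U and Uextra) and on the mitochondrial genome. The median signal per array lay between 182 and 950 in Cy3 and between 143 and 1046 in Cy5. The number of arrays, not the number of probes, limited the precision. All values below are log2 ratios of embryo DNA over reference, centred on the median of each array, and all positions are on dm3.

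The first comparison asked whether each labelled deletion removed its arm. Without 2L, probes on 2L fell to a mean array median of -4.37 ± 0.34 (SD, n = 2), against 0.07 ± 0.18 (SD, n = 8) where the arm was present, which is 21.8-fold lower. Without 2R the probes on 2R fell 16.9-fold, to -4.01 ± 0.10 (SD, n = 2). Without 3L those on 3L fell 11.4-fold, to -3.52 ± 0.45 (SD, n = 2), and without 3R those on 3R fell by 3.33 on the log2 scale, to -3.31 ± 0.70 (SD, n = 2). Without the X, probes on the X fell 7.81-fold, to -2.98 ± 0.55 (SD, n = 2). In 4- embryos the median of the 234 probes on chromosome 4 was -4.62, against -0.11 ± 0.23 (SD, n = 9) in the others, whose lowest value was -0.56. In each of the 5 tested arms the difference was larger than the spread between arrays, and every array without the arm lay below every array with it. The two-sided exact permutation test gave p = 0.0444 for each arm, the smallest value that 2 of 10 arrays can give, and 0.0444 after Benjamini-Hochberg adjustment over the 5 arms. For the chromosome 4 median, with 1 array against 9, no exact permutation test could pass 0.05; its probes were tested singly. The size of the drops depended on the processing: X, 2L, 2R, 3L and 3R differed by -2.17, -2.49, -2.24, -2.15 and -2.05 with the values deposited by the submitters, and by -2.91, -3.14, -2.72, -1.99 and -1.87 with loess within arrays.

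**Figure D1:**
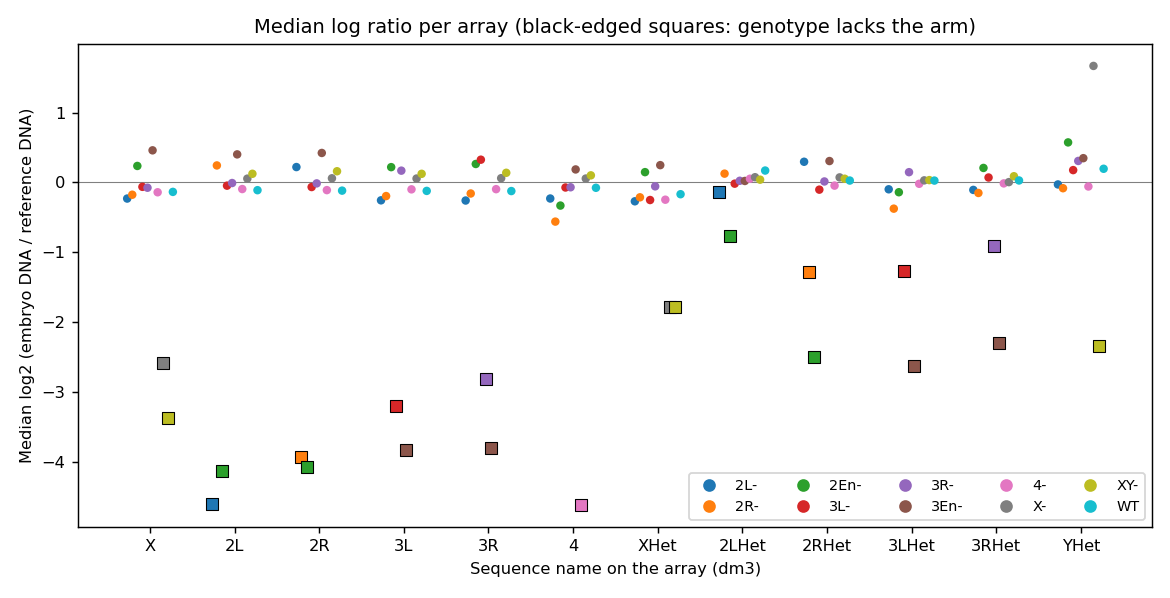
Median log2 ratio (y axis) of the probes on each euchromatic arm, on chromosome 4 and on each placed heterochromatin scaffold, including YHet. Each array is a point, with arrays that lack the sequence marked apart from those that carry it. For X, 2L, 2R, 3L and 3R both arrays without the arm sit below -2.5, and the arrays with it lie between -0.26 and 0.46.

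Slides and scans did not remove these differences. Of the 7 slides 3 held 2 arrays each, and the arrays were scanned in 4 sessions, the largest of which (scan 2) held 6 arrays. Within scan 2 the difference between arrays without and with the arm was -2.96 for X, -4.21 for 2L, -4.04 for 2R, -3.28 for 3L and -2.94 for 3R. Within scan 1 it was -4.50 for 2L. Between the arrays of 1 slide it was -4.38 for 2L, -3.38 for 3L and -3.14 for 3R. With the scan as a block it was -2.96 for X, -4.32 for 2L, -4.04 for 2R, -3.28 for 3L and -2.94 for 3R. Both arrays without the X shared a slide, as did both arrays without 2R, so no value within a slide could be had for these 2 arms. On the same slides other arms moved less. In 2R- the X, 2L, 3L, 3R and chromosome 4 measured -0.18, 0.24, -0.20, -0.16 and -0.56, and in 2En- the X, 3L, 3R and chromosome 4 measured 0.24, 0.22, 0.26 and -0.33. In X- 2L, 2R, 3L and 3R measured 0.05, 0.06, 0.06 and 0.06, and in XY- 0.12, 0.16, 0.12 and 0.14. XY- and WT ran in the same dye orientation, and their ratios correlated over all probes with r = -0.387 in the table deposited by the submitters and -0.167 in the scanner values; the direction was kept because the labels state the dyes.

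Single probes were tested to find which sequences went with each arm, placed or not. At a limma adjusted p under 0.05 and a log2 difference of -1 or lower, 11653 probes fell without the X, 7708 without 2L, 10069 without 2R, 9903 without 3L, 10349 without 3R and 174 without chromosome 4, the last with a lone array assumed to vary like the others. On the arm itself the share of tested probes that fell was 83.4% for X, 89.7% for 2L, 91.1% for 2R, 88.4% for 3L, 88.7% for 3R and 63.6% for chromosome 4. Probes that rose past the same limits numbered 5, 13, 344, 0, 3 and 0. Large numbers of the called probes had no position: 8499 without the X, 4104 without 2L, 5824 without 2R, 5942 without 3L, 5293 without 3R and 27 without chromosome 4. Loess within arrays lowered the counts to 4435 without 2L, 6430 without 2R, 4129 without 3L and 5199 without 3R, while 178, 344, 31 and 8 probes rose. With the scan as a block, 1034 probes rose without 2R. When 1 array that carries 2R was left out, that number ran from 268 (X- left out) to 529 (3En- left out). Leaving out the 3L- array raised the count without 3L to 19659, and leaving out the 3R- array raised the count without 3R to 18038, while 1246 and 1150 probes rose. Each then rests on 3En- alone, which lacks both arms, so these are not counts of 1 arm. An additive limma fit of all arms, with 2 residual degrees of freedom, called 0 probes without 3R, chromosome 4 or the Y, where 11739, 2578 and 6108 probes had an unadjusted p under 0.05.

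Chromosome 2 was examined at its proximal ends, where euchromatin passes into pericentric heterochromatin. Of the genes listed beforehand for proximal 2L, all 7 with 3 or more probes fell. RpL5, a ribosomal protein gene at 2L:22427533-22428984, fell 15.9-fold. The vesicle trafficking gene lt (2L:22832152-22833488) fell 12.6-fold. The histone genes His1 and His4, which stand in a tandem array, fell 134-fold and 48.3-fold, although the 5 probes of His1 lay on Uextra. On proximal 2R, 4 of 5 listed genes with 3 or more probes fell. The cohesin loader gene Nipped-B (2R:579336-614539) measured -5.06 in 2R- and -5.33 in 2En-, a 37.5-fold drop. The exception was rl, the MAP kinase gene of the Ras pathway, at 2RHet:207287-251734. Its median was -1.07 in 2R- and -4.75 in 2En-, and 3 of its 6 probes fell. Counted over genes with 1 or more probes, 9 of 9 genes fell for 2L and 9 of 10 for 2R. The 9 for 2R include Yeti, with 1 probe on 2RHet, which measured -0.57 in 2R- and -2.73 in 2En-. Its fall thus came mostly from 2En-, like that of rl. Of the list's probes 34 of 36 were called for 2L both over all probes and adjusted over the list alone, and for 2R 23 of 26 over all probes and 26 adjusted over the list alone.

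The split seen at rl also appeared in the first 3 windows of the 2RHet scaffold. The 2RHet median fell to -1.28 in 2R- and to -2.50 in 2En-, against 0.08 ± 0.15 (SD, n = 8) in arrays with 2R. Relative to the median of the arrays with the arm, the window at 2RHet:1-250000 lay at -0.53 in 2R- and -4.05 in 2En-, and the next, 250001-500000, at -0.66 and -2.78. At 500001-750000 the values were -2.21 and -4.48, and at 1500001-1750000 they were -3.97 and -3.67. The gene l(2)41Ab (2RHet:494755-570571) measured -1.29 in 2R- and -5.38 in 2En-, whereas CG17684 (609292-738362), in the window that starts at 500001, was low in both at -5.79 and -6.98, and Scp1, a calcium-binding protein gene at 1707841-1707900 with 1 probe, -5.96 and -6.96. CG17514, placed at 2RHet:2776047-2821076, did not go with chromosome 2: it measured -0.77 in 2R-, -0.65 in 2En- and -4.10 in 3En-. Of 12 windows on 2RHet 9 were low in 2R- and 10 in 2En-. All 12 windows over the last 3 Mb of euchromatic 2L and all 12 over the first 3 Mb of 2R were low in both deletions of that arm. The 2LHet median fell least, by 0.51 on the log2 scale (37 probes), and of its 36 tested probes 9 fell. The array 2L- measured -0.13 and 2En- -0.76 on 2LHet, so most of that difference came from 2En-: it was -0.19 without the 2En- array, -0.82 without the 2L- array and -1.12 as a mean over probes. Its exact permutation p was 0.267 when arrays were centred on the euchromatic arms they keep. The arrays 2R- and 2En- shared a slide, and chromosome 4 and mitochondrial probes also stood apart in them (-0.56 and -0.33 for chromosome 4). They also had the largest GC trends, 0.38 and 0.67 between probes of 35% and 45% GC, with 0.31 next in 3En-. Whether that trend lowered chromosome 4 in them was not tested.

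**Figure D2:**
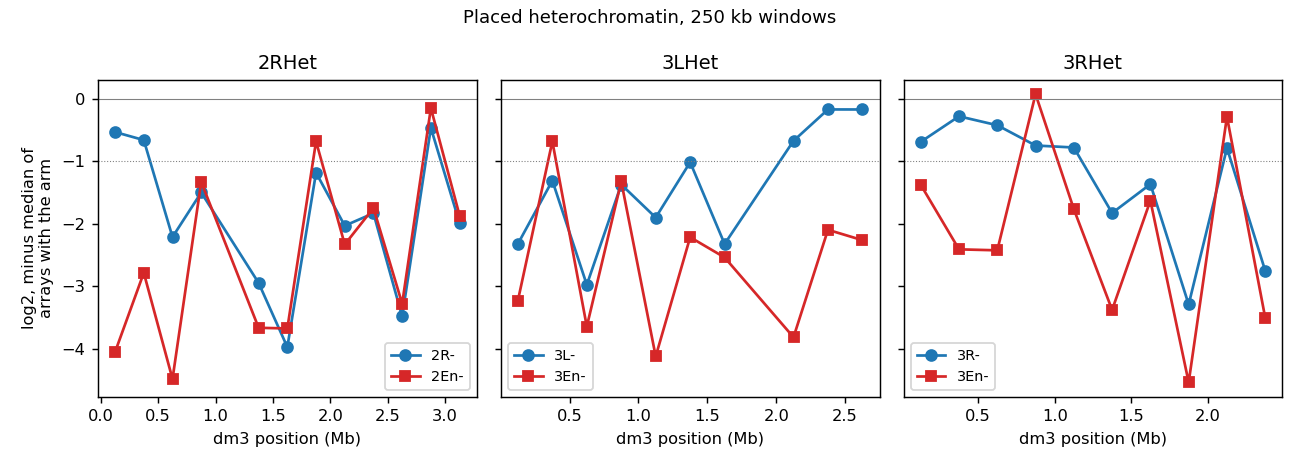
Median log2 ratio in windows of 250 kb along the placed heterochromatin of 2R, 3L and 3R (x axis, position on the scaffold), relative to the median of the arrays with the arm, for the arm deletion and for the deletion of both arms. At the start of 2RHet the 2R- window is -0.53 and the 2En- window -4.05, whereas they lie at -3.97 and -3.67 in the window 2RHet:1500001-1750000.

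Chromosome 3 had the same kind of region on both sides of its centromere. The scaffold 3LHet fell to -1.27 in 3L- and -2.62 in 3En-, against -0.05 ± 0.16 (SD, n = 8) in arrays with 3L. The scaffold 3RHet fell to -0.92 in 3R- and -2.31 in 3En-, against 0.02 ± 0.11 (SD, n = 8). On euchromatin too 3En- read lower than the lower of the 2 arm deletions, by a median of 0.70 on 3L and 1.08 on 3R over single probes, so part of these gaps is not specific to the scaffolds. On 3LHet, Set1, which encodes a histone methyltransferase (594860-600555), fell 7.97-fold and measured -2.93 in 3L- and -3.49 in 3En-. Further along the scaffold, CG40228 (2188918-2190339) measured -0.21 in 3L- and -4.40 in 3En-, and Dbp80, an RNA helicase gene (2423836-2544149), measured -0.15 and -2.94. Neither passed the test without 3L, with median limma adjusted p of 0.269 and 0.135. On 3RHet, CG41133 (421930-435790) measured -0.07 in 3R- and -2.93 in 3En- and did not pass (limma adjusted p = 0.290), while Parp, the poly(ADP-ribose) polymerase gene (2026624-2027161), fell 17.4-fold with -3.35 and -5.01. Gfat1, an enzyme gene of hexosamine synthesis (2476857-2481548), fell 10.7-fold with -3.17 and -3.62. The windows at 3LHet:2250001-2500000 lay at -0.17 in 3L- and -2.10 in 3En-. The window at 3RHet:250001-500000 lay at -0.28 in 3R- and -2.41 in 3En-, and 1750001-2000000 at -3.29 and -4.54. Of 10 windows on 3LHet 7 were low in 3L- and 9 in 3En-, and of 10 on 3RHet 4 were low in 3R- and 8 in 3En-. All proximal euchromatic windows were low in both deletions of their arm except 1 of 13 on 3L, which was not low in 3L-. Of the listed genes with 3 or more probes, the rule fixed beforehand, 0 of 1 fell for 3L and 0 of 1 for 3R. With 1 or more probes, a rule chosen after the data were seen, 5 of 8 fell for 3L and 1 of 3 for 3R. The 5 for 3L include nvd, which had no value in 3L- and rests on 3En- alone, at -3.55. Of their probes 7 of 13 were called for 3L over all probes and 10 adjusted over the list alone, and for 3R 2 of 8 either way. Some listed genes lay on the other arm by the array's positions, which limits these tallies. Set1 and Alg10 stood in the list for 3R but lay on 3LHet and 3L, and Set1 measured 0.13 in 3R-. The gene spok stood in the list for 3L but lay on 3RHet.

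The 5 scaffolds named for an arm were tested together. Their medians differed by -1.69 for XHet (20 probes), -0.51 for 2LHet (37, -0.19 without the 2En- array), -1.96 for 2RHet (124), -1.90 for 3LHet (105) and -1.63 for 3RHet (89). The last 3 also shrank without the whole-chromosome deletion, to -1.36 for 2RHet without 2En- and to -1.22 for 3LHet and -0.93 for 3RHet without 3En-. The two-sided exact permutation test gave p = 0.0444 for each, also after Benjamini-Hochberg adjustment over the 5. Because that is the smallest p, a change of rank in 1 scaffold ends the adjusted call of all 5, as it did under 3 of the normalizations through 2LHet.

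Sequence lost only when both arms were gone was counted next, since it lies outside what either arm deletion removes. A probe counted here when the whole-chromosome deletion lay 1 or more below the mean of the 7 arrays of other stocks and neither arm deletion did, whatever those 7 arrays showed singly. By that rule there were 17 probes on 2RHet for 2En-, and 16 on 3LHet and 22 on 3RHet for 3En-. No background rate is given for these counts. On other chromosomes some of the 7 arrays lack the arm, so their mean is itself low. On euchromatin of the same chromosome 1 arm deletion already lowers most probes. There the rule gave 25 of 3910 probes on 2L and 22 of 4444 on 2R for 2En-, and 29 of 4330 on 3L and 70 of 5539 on 3R for 3En-. The rule also gave 11 of 124 2RHet probes for 3En-. This is not a rate of false calls alone, because the window 2RHet:2750001-3000000, which holds CG17514, had a median of -3.13 in 3En-. Among probes without a position there were 3065 for 2En- and 6669 for 3En-. Some of the latter matched the dodeca satellite, a short GC-rich tandem repeat with the unit ACCGAGTACGGG. The 869 probes of this repeat, sought after the values were seen, were low in 3En- and in no other array. They had a median of -4.64 in 3En-, 35.9-fold below the other 9 arrays (0.53 ± 0.47, SD, n = 9). In 3L- the median was 0.22 and in 3R- it was 0.09.

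The X and Y were compared through X- embryos, which come from a cross in which both parents can give a Y, and XY- embryos, which have neither. Several genes near the base of the X fell in both, although only 12 of 20 probes on XHet were called. The gene fog (X:22228014-22255678), which encodes a secreted signal for gastrulation, fell 6.42-fold, with -2.90 in X- and -3.34 in XY-. The mRNA processing gene su(f) (XHet:77844-79939) measured -2.15 and -2.50, and CG17167 (XHet:58881-59542) measured -3.44 and -5.80. DIP1, at X:21495914-21497161, measured -1.36 and -0.67, and 1 of its 3 probes fell (median limma adjusted p = 0.200). Of the listed X genes, 1 of 2 with 3 or more probes fell, and 5 of 6 with 1 or more. Of their probes 10 of 12 were called over all probes and 12 adjusted over the list alone. All 12 proximal windows of the X were low in both genotypes.

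Y sequences went in opposite directions in the 2 genotypes. The 17 probes on YHet had a median of -2.34 in XY-, 1.67 in X- and 0.18 ± 0.23 (SD, n = 8) in the arrays with an X. The difference of -2.52 between XY- and the arrays with an X was -1.48 with normexp and -1.34 with the deposited values. Within scan 2, the difference between XY- and the mean of the other 5 arrays was -2.87, and the difference from X- on the same slide was -4.01. The dynein heavy chain gene kl-2 (YHet:82994-148248), needed for sperm motility, measured -3.37 in XY- and 1.80 in X-. ORY (271391-271450) measured -3.18 and 1.84, and Ppr-Y (206187-206246) measured -4.56 and 1.90. Of the listed Y genes 6 of 8 with 1 or more probes fell in XY-, while none had 3. By the array's positions PRY, which fell, lay on U, and ARY, which did not pass, on 3LHet. Of their 11 probes 9 were called over all probes and 9 adjusted over the list alone. Over the array 12432 probes fell in XY-, a lone array assumed to vary like the others. Of these 10963 were also at -1 or lower in X-, 426 lay between, and 1026 were at 1 or higher in X-. In X- 155 probes rose, of which 152 also fell in XY- and 143 had no position. This count ranged from 15 to 511 when 1 array was left out, the lowest without WT and the highest without 3En-, and each rests on a lone X- array.

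Chromosome 4 was absent from 1 array only, of embryos aged 23 to 24 h by their stage label (another note in the labels gives a wider range). The test set this lone array, of older embryos, against 9 and took its spread from the others. All 17 listed genes of this chromosome had a median difference of -1 or lower, and 12 of them also passed the test in most of their probes. Of 8 genes with 3 or more probes 7 fell. Crk, an adaptor protein gene (4:233290-233656), measured -7.29 and lay 128-fold lower. PlexB, a semaphorin receptor gene (53458-53967), measured -7.59, or 170-fold lower, and the Hedgehog pathway transcription factor gene ci (68613-77423) measured -6.68. The Wnt pathway transcription factor gene pan (113844-129430) measured -3.15, and 2 of its 5 probes fell. Of the list's 49 probes 34 were called over all probes and 49 adjusted over the list alone. Of the 234 probes 13, or 5.56%, were not well above background in 4- embryos, so their drop is a lower bound. The count of 174 became 113 with the values deposited by the submitters and 104 without the WT array.

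Unplaced sequence was then assigned by the set of arrays in which it was low. Only 1 window of 10 kb in U and Uextra held 5 probes and followed a rule: Uextra:220001-230000, with 6 probes, measured -4.07 in 2L- and -3.32 in 2En- and went to 2L. The same rule on single probes returned 81.2% of placed X probes to the X, 83.6% of 2L, 86.1% of 2R, 80.9% of 3L, 82.5% of 3R and 77.4% of chromosome 4 to their own arm. It also gave 26 of the 29 mitochondrial probes to chromosome 4, since they too were low in 4-. Of the 56671 probes without a position it gave 7778 to the X, 3328 to 2L, 4692 to 2R, 4664 to 3L, 4241 to 3R, 445 to chromosome 4 and 2269 to the Y or to X and Y together. By this stricter rule, which also asks that no other array be low, 1004 went to 2En- alone and 5624 to 3En- alone. Both arm deletions and the whole deletion were low for 16 on chromosome 2 and 358 on chromosome 3. The remaining 8902 were low in no array and 13350 in other sets. Over the alternatives run, the class of chromosome 4 ranged from 201 to 1436 probes and that of the X from 6770 to 7832. The probes given to the X were bright, with a median Cy3 signal of 19523, and measured -2.88 in X- and -4.39 in XY-. Those given to the Y or to X and Y measured 1.37 in X- and -1.86 in XY-. The 445 given to chromosome 4 measured -2.22 in 4- and 1.11 in 2R-, unlike the probes placed there (-4.62 and -0.56). Those low only in 3En- had a median GC content of 56.7%.

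**Figure D3:**
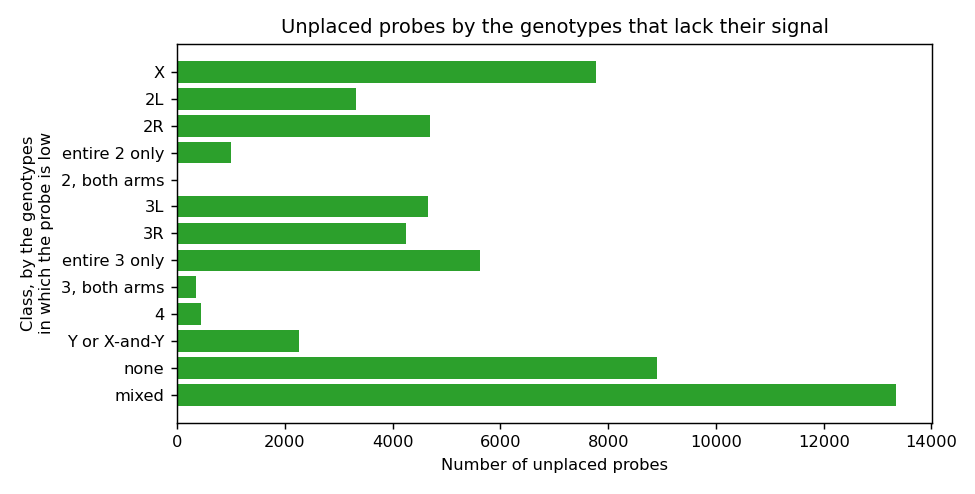
Number of probes without a position (x axis) assigned to each chromosome or arm by the set of arrays in which they are low, one bar per class. The X has the largest single class of an arm, 7778 probes, and 5624 probes are low only in 3En-.

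The dose of the arms that compound stocks keep was compared with the same arm in other stocks. In 2L- the retained 2R lay 0.17 above the mean of the other 7 arrays with 2R, against an SD of 0.19. In 2R- the retained 2L lay 0.20 above, in 3L- the retained 3R 0.35 above and in 3R- the retained 3L 0.21 above, against SDs of 0.18, 0.18 and 0.18. The difference was thus below that SD for 2R in 2L-, and above it for the other 3. These SDs also hold shifts of whole arrays: 2R measured 0.42 in 3En- and -0.12 in WT. Within 2L- itself 2R measured 0.22, against -0.23, -0.26 and -0.26 on X, 3L and 3R. In 2R-, 3L- and 3R- too the retained arm, at 0.24, 0.33 and 0.17, read above the X and both arms of the other large chromosome. When each array was centred on the arms outside the chromosome altered in its own stock, the differences were 0.47, 0.42, 0.38 and 0.21, or 1.38, 1.33, 1.30 and 1.15 as ratios. Arrays of other stocks were then centred on sets of arms that include the arm compared, which draws their values together. Their SDs, between 0.01 and 0.02, therefore understate the spread between arrays, and the differences cannot be judged against them. Each value rests on 1 array, so no test was run.

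Wild type blastoderm DNA differed little from the mixed-stage reference in the medians of arms and scaffolds. Its medians were -0.14 on the X, -0.11 on 2L, -0.12 on 2R, -0.12 on 3L, -0.12 on 3R and -0.08 on chromosome 4. On scaffolds they ran from -0.17 on XHet to 0.20 on YHet. Some repeat probes stood further off in WT. The complex satellite of the X measured 1.36, dodeca 0.24 and AATAACATAG -0.57, and the unplaced probes given to the X measured 0.72. The other arrays with an X also read high on the complex satellite, at 1.11 to 1.53. The cause was not tested. Heterochromatin minus euchromatin was 0.19 in WT embryos of 2.5 to 3.5 h and 0.11 in 4- embryos of 23 to 24 h. In the 8 arrays of 3.5 to 8 h it was -0.04 ± 0.15 (SD, n = 8). Neither stage lay outside the range of these 8 arrays, of which 2L- also measured 0.19. That range also holds effects of the deletions, because U and Uextra probes were kept for every genotype. It therefore cannot exclude an effect of stage.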

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

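The tests of the mitochondrial signal and of the dodeca repeat were chosen only after the results were seen; the tests of the residual signal were set before them, apart from an upper bound and the test without the brightest probes, which were added later.

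Y-linked sequence moved in opposite ways in the 2 genotypes without an X. The YHet median lay 1.49 above the mean of the 8 arrays with an X in X- embryos, and at -2.52 relative to that mean in XY- embryos. Each rests on 1 array, and the difference between them was not tested.

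Mitochondrial probes were part of the probe fits, where 5 of 29 rose and 1 fell without 2R, but no comparison was planned for them. They were well above the wild type level in 2 arrays: 1.13 above in 2R- and 0.85 above in 2En-, with 4- far below at a median of -2.28 (29 probes). A GC trend does not account for the first 2, since with the trend removed the higher of them stood 5.20 SD above the mean of the other 7 arrays. Less nuclear DNA per embryo where arms are missing is argued against by 3En-, which lacks as many arms as 2En- yet lay at -1.09 relative to WT. Age cannot be the whole cause, because the highest array of 3.5 to 8 h exceeded the younger WT embryos by 1.13, although the low value of 4- goes with the oldest embryos. The lack of 2R and the slide that 2R- and 2En- shared cannot be told apart, and both may play a part.

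Absent arms kept a residual signal of 3.89% to 16.8% of the level in arrays with the arm, on the median probe. Intact embryos mixed into the sample would give dim and bright probes a like share, but with probes in 4 equal groups by brightness the brightest kept 3.23 times the share of the dimmest (median of 11 array and arm pairs, range 1.66 to 10.7), so mixing cannot be the whole cause. Background at single probes was predicted to bring that ratio under 0.5 and is argued against by the same 3.23. Without the brightest group the share was within 1.5 times in 8 of the 11 pairs, with the third group at 1.25 times the dimmest (range 0.968 to 1.73), and the dimmest group kept 60.7% to 91.5% of the median residual. Mixed-in intact embryos may account for some of that part, but not all, since mixing leaves every probe of an arm the same share. In 4- the dimmest group kept 3.34%, whereas Crk lay 128-fold and PlexB 170-fold lower, genes picked after their values were seen. Most listed genes of chromosome 4 fell less far than these. An array-wide narrowing of ratios, and hybridisation of related sequence from other arms to the brightest probes, were not tested and stay open.

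Probes of the dodeca repeat were low in 3En- but in neither arm deletion of chromosome 3. Removing the GC trend left the difference at -5.95, so that trend is not its cause, and saturation, found in 0.115% of the probes, cannot hide a loss in 3L- and 3R-. The lower of the 3L- and 3R- medians lay at -0.54 relative to the 7 arrays that keep chromosome 3, whose SD was 0.48. This is consistent with compound 3L and compound 3R chromosomes that both carry the repeat. No biological alternative, such as a different copy number between stocks, was tested.

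Among 13 groups of arrays that could be tested for a single array far from the rest, 0 held one; chance gives about 1 in 20.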

How the results depend on the processing

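The GC correction, scan and slide as fixed blocks, scan 2 alone, and gene lists with 1 or more probes were chosen only after the results were seen.

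Arm medians kept their direction in every alternative, but not their size. For X, 2L, 2R, 3L and 3R they were -2.19, -2.78, -2.76, -2.40 and -2.36 with normexp, -2.91, -3.14, -2.72, -1.99 and -1.87 with loess, and -2.17, -2.49, -2.24, -2.15 and -2.05 with the deposited table. The YHet difference in XY- was -1.48, -2.12 and -1.34 in these 3, and -2.10 as a mean. With arrays left out in turn they ran from -3.36 to -2.57 (X), -4.68 to -4.20 (2L), -4.15 to -4.01 (2R), -3.83 to -3.19 (3L) and -3.82 to -2.84 (3R). Fewer arrays allow no p below 0.0556, so none passed. In scan 2 alone they were -2.96, -4.21, -4.04, -3.28 and -2.94, with a smallest p of 0.133. Chromosome 4 was -3.50 with normexp, -3.19 with the deposited table and -4.12 as a mean; the cause was not tested. The 5 scaffolds became 0 with centring on kept arms, loess or the deposited table, because the adjusted call needs all 5 at the smallest p and 2LHet reached 0.267, 0.0889 and 0.0889. They also became 0 with scan 2 alone or any array left out (0 to 0), where no p can pass. Without 3En- the 3LHet and 3RHet differences shrank to -1.22 and -0.93, and without 2En- those of 2LHet and 2RHet to -0.19 and -1.36.

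Loess gave 4435 probes without 2L, 6430 without 2R, 4129 without 3L, 5199 without 3R, beside 178, 344, 31 and 8 in the opposite direction, and 536 higher in X-; it turned 2 genes, nvd without 3L to 0.47 and Set1 without 3R to 0.34. Other counts of probes higher in X- were 1 (adjusted p under 0.01), 406 (kept arms), 481 (deposited table), 100 (GC trend removed), 7 (additive fit), 1296 (array weights), 83 (slide as a random block), 39 (scan as a block), 26 (scan 2), and 15 to 511 with arrays left out: 34, 56, 272, 26, 42, 511, 26 and 15 without 2L-, 2R-, 2En-, 3L-, 3R-, 3En-, 4- and WT. Without chromosome 4 the count was 96 (adjusted p under 0.01), 113 (deposited table) and 104 to 197 with arrays left out, lowest without WT. Without 3L and 3R, scan 2 alone gave 5797 and 4289, and slide as a fixed block 6612 for 3R, beside 6429 probes in the opposite direction, because that fit sets 3R- against 3L- on their shared slide; with arrays left out they ran from 8319 to 19659 and 8297 to 18038, highest without 3L- and 3R-, where 3En- alone, which lacks both arms, is left and 1246 and 1150 went the opposite way. Scan as a block gave 1034 in the opposite direction without 2R. The additive limma fit, with 2 residual degrees of freedom, gave 3605 (X), 6594 (3L) and 0 for 3R, 4 and Y, where 11739, 2578 and 6108 probes had an unadjusted p under 0.05 and a negative difference; list genes fell to 11 of 19, or 20 of 47 with 1 or more probes. The 1 assigned window was lost (0) with 10 probes per window, low at 0.5, or loess. Unplaced probes given to the X ranged from 6770 to 7832, to chromosome 4 from 201 to 1436, and to no array from 3593 to 13103. Lists with 1 or more probes gave 47 genes. For other changes than those from fewer arrays or tests the cause was not tested.

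Of 29 gene results, 22 moved with normexp and 23 with the deposited table, and 29 held without a filter on dim probes. Centring on kept arms shifted medians by -0.42 to 0.18. Dim signal limits the drop: of probes on 3L and 3R, 5.28% and 5.19% were not well above background in at least 1 array without the arm. Leaving out 4-, X- or XY- gave no value for comparisons that rest on that array alone, and slide as a fixed block could be fitted only for 2L, 3L and 3R. No paired analysis was possible because each genotype has 1 array.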

Other observations

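All tests here were chosen only after the results were seen.

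Repeats known from the X followed it. The 462 probes of the complex AT-rich satellite of X heterochromatin had a mean of -3.14 ± 0.75 (SD, n = 2) without the X and 1.32 ± 0.14 (SD, n = 8) with it, 22.0-fold lower (exact permutation p = 0.0444). The higher of the 2 genotypes lay at -3.93 relative to the arrays with an X, consistent with a repeat carried on that chromosome, and 409 of these probes had been assigned to the X. The 133 probes of the AATAACATAG repeat, sought as a repeat of chromosomes 2 and 3, did not show the drop of 1 or more that was predicted. The lower of 2En- and 3En- lay at -0.18 relative to WT. A repeat on both chromosomes would keep copies when either is absent, so this test cannot tell where the repeat lies. No probe held enough of the AAGAG or AATAT repeats.

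Ribosomal RNA probes were mixed. Of 14, 8 were lower by 1 or more in XY- than in WT, and 4 of these, or 50%, were not so in X-. This is a share of probes, not of signal. A probe with copies on both X and Y could pass that cut in X- through the loss of its X copies alone. The count therefore does not settle whether rRNA genes lie on both X and Y. The 4 not so in X- were CR40597, CR40779, CR41550 and CR41608, named after their values were seen, on 1 probe each. They measured -4.53, -1.41, -6.22 and -6.34 in XY-, 0.70, -0.64, -0.52 and -0.53 in X-, and 1.52, 0.27, 0.16 and 0.35 in WT. CR41609, with 1 probe, was lower by 1 or more in both, at -5.47 in XY- and 0.10 in X- against 1.16 in WT. At CR41609, CR40597, CR41550 and CR41608, X- embryos thus kept signal that XY- embryos lacked. CR41610, with 3 probes, was low in both, at -4.52 in XY- and -2.84 in X-.

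The 445 unplaced probes low only in 4- may include sequence other than chromosome 4. Of the 376 with values on all arrays, 46.3% followed the mitochondrial median over the other 9 arrays (r of 0.8 or higher), against 0 of 232 probes placed on chromosome 4. None of the 18 that were called without chromosome 4 did (0 of 18). The same assignment rule gave 26 of 29 mitochondrial probes to chromosome 4, and the class median was 1.11 in 2R- and 0.99 in 2En-, where probes placed on chromosome 4 measured -0.56 and -0.33. A part of the class therefore read like mitochondrial sequence, but r was under 0.5 in 135 probes, and the source of the rest cannot be told apart.

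The 4- array read lower on mitochondrial genes throughout, with COX1 at -2.22 and CYTB at -2.30, while COX1 measured 1.46 in 2R- and 1.57 in 2En-.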
